A study of Mus musculus with 6 samples.

How the data were processed

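Total RNA from snap-frozen liver of 6 mice was extracted with TRIzol and a column kit, and biotinylated material for Affymetrix arrays was made from 100 ng of RNA, per the labels. The labels place 4 arrays in the Pcyt2+/- group and 2 in the wild type group, with separate mice named in the titles. The titles call the first group knock-out, while the genotype field gives Pcyt2+/-, which is used here. The deposited values are log2 expression per probe set, made by the authors with RMA per the submitters' processing notes. The version of RMA and the genome build were not given in the sources used here, and no coordinates are printed.

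The deposited table held 28996 probe sets for 6 arrays with no missing value, from 3.96 to 13.02. Array medians lay at 4.40 on each array, and the number of probe sets above 5 ran from 1557 (Pcyt2+/- replicate 3) to 1637 (wild type replicate 4). In the platform annotation 21218 probe sets had 1 gene symbol, 1881 had several and 5897 were unnamed here. Of the probe sets with 1 symbol, 21185 matched the RefSeq gene table of assembly GRCm38.p6 by gene identifier, which changed 0 symbols. That table was used for names and for which genes neighbour each other. Where a gene had several probe sets (1386 genes), the one with the highest mean over all arrays stood for it, which gave 18820 genes. Probe sets with several symbols or unnamed here (7778) were tested only with every row of the table in 1 fit, where 0 of them passed by limma and 357 had an unadjusted p under 0.05. For arrays there is no sequencing depth, and the number of arrays limits the precision.

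Differences are Pcyt2+/- minus wild type on the log2 scale. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with its default prior, two-sided, no covariates, all 6 arrays), with Benjamini-Hochberg adjustment over 18820 genes and a threshold of 0.05. Pcyt2 was also tested with a two-sided exact permutation test over 15 splits. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over 38 lists, with the estimated correlation and fry beside it. With a preset correlation camera takes its degrees of freedom from the number of genes. With an estimated one it takes the 4 residual degrees of freedom of the arrays. The p-values at the preset correlation therefore do not measure the spread between mice. The 38 lists (21 pathways, 7 of sex, clock, handling and fasting state, and 10 of cell type markers) held 979 genes, of which 856 were measured, and some genes stand in more than 1 list. Counts adjusted over the list alone apply Benjamini-Hochberg to limma's p within a list and do not allow for the number of lists. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

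The groups, tests, lists, the first set of other settings and the rule for naming genes were set before the data were examined. The rule took Pcyt2. It took up to 12 genes in each direction with an adjusted p under 0.05 and ranges that did not overlap, and filled empty places, by unadjusted p, with genes of an absolute difference of at least 0.5 and ranges that did not overlap. Predicted genes, clones and small RNAs were passed over for these places. As 0 genes passed, 12 lower and 5 higher genes came in by the fill. The rule also took, per discussed list, each member with an adjusted p under 0.05 over all genes and otherwise up to 4 members with the smallest unadjusted p, and a fixed set of regulators, of which 14 are reported here. A list was discussed where camera's adjusted p was under 0.05 or a member passed when adjusted over the list alone.

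The steps were tested on simulated data with the spread of the real genes, 4 against 2 arrays and 18820 genes. Of genes changed by 0.25, 0.50, 1.00 and 2.00 on the log2 scale, 97.8%, 66.4%, 91.6% and 98.4% were recovered, where the 0.25 changes were given to dim genes with little spread. Each size was given to 500 genes over 10 simulations, and many changed genes ease the Benjamini-Hochberg adjustment. Recovery may thus be lower in the real data, where none of the 6 genes with an absolute difference of at least 1 passed. Of unchanged simulated genes 0.041% were called. Of 370 unshifted lists, 3 were called with the preset correlation and 0 with the estimated one. Genes were simulated independently of one another, so these list rates do not cover lists whose members vary together. In the real data the estimated correlation was 0.24 for oxidative phosphorylation and 0.17 for cholesterol synthesis, against the preset 0.01. It was 0.0017 for the glucocorticoid response and -0.018 for gluconeogenesis, below the preset.

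The other settings fixed in advance were a filter on dim genes, every row of the table, the mean of a gene's rows, quantile normalization, median centring, a trended and robust prior, the unmoderated statistic, array weights, a replicate block, and leaving out each array. For lists they were the estimated correlation, fry, the dim gene filter, quantile normalization, the replicate block and leaving out each array. The dim gene filter kept genes with a mean at or above the median of all row means (4.40), so it also kept many genes with a mean below 5. Settings chosen after seeing the data were genes with a mean above 5, subtraction of each array's median on the linear scale for genes with a mean above 4.6, and lists without the Cyp4a genes or without Pcyt2. Replicate numbers 3 and 4 are the ones both groups share, and nothing in the labels says that a number marks a shared litter or day. The replicate block therefore compared the genotypes only within replicates 3 and 4, as Pcyt2+/- replicates 1 and 2 had no wild type partner. For outlying arrays, Dixon's test was run on the 4 Pcyt2+/- arrays, since 2 wild type arrays are too few. No sample was left out.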

Results

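Gene expression was measured in the livers of 2-month-old C57BL6 mice that carried the Pcyt2+/- genotype and of wild type mice of the same age. Pcyt2 encodes the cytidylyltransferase that makes CDP-ethanolamine, the regulated step in the synthesis of phosphatidylethanolamine. The labels give 4 Pcyt2+/- mice (replicates 1 to 4) and 2 wild type mice (replicates 3 and 4), each with its own array. The deposited log2 values covered 28996 probe sets, of which 18820 genes were tested. Most of the array lay in a narrow band at low signal: 94.4% of probe sets had a mean between 4 and 5, 5.55% had a mean above 5, and the highest value was 13.02. Arrays correlated at Pearson r of 0.991 to 0.998 across probe sets, which are not independent of one another, with 0.996 between both wild type arrays. The array of Pcyt2+/- replicate 3 had the lowest value, 0.991 with wild type replicate 4. The sex of the mice and their feeding state at collection were not given in the sources used here. The number of arrays limits the precision of every comparison.

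Pcyt2 itself had a lower signal on each of the 4 Pcyt2+/- arrays than on either wild type array. The log2 values were 4.638, 4.657, 4.669 and 4.604 on the arrays of Pcyt2+/- replicates 1 to 4, and 4.887 and 4.796 on those of wild type replicates 3 and 4. The group means were 4.64 ± 0.028 (SD, n = 4) and 4.84 ± 0.064 (SD, n = 2), a difference of -0.20 with an SE of 0.028 and a 95% interval of -0.27 to -0.13. The difference did not pass limma over all genes (adjusted p = 0.264). In the two-sided exact permutation test over the 15 splits of the arrays its p was 0.0667, the smallest that 4 against 2 arrays can give, so that test cannot reach 0.05. Pcyt2 lay in the low band of the array, and the difference was -0.97 once each array's median signal was subtracted on the linear scale, a setting chosen after seeing the data (adjusted p = 0.0671). Whether the probe set lies in the altered part of the gene was not given in the sources used here.

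The comparison of Pcyt2+/- with wild type liver asked which genes differ when Pcyt2 is deficient. The lowest value relative to wild type belonged to Cyp4a14, a fatty acid omega-hydroxylase, at 6.66 ± 0.39 (SD, n = 4) against 9.22 ± 0.19 (SD, n = 2), a log2 difference of -2.56 or a 5.89-fold higher signal in wild type. Cyp4a31, of the same family, differed by -1.15 (9.13 ± 0.19 against 10.27 ± 0.023). Tat, which starts tyrosine breakdown, differed by -1.13 and Mt2, a metal-binding metallothionein, by -1.07. On the higher side stood Serpina4-ps1, a serpin pseudogene (1.07), Cyp2c70, which makes muricholic acids (1.05), and Car3, an abundant liver carbonic anhydrase (0.88; 10.58 ± 0.057 against 9.69 ± 0.45; 0.57 without wild type replicate 4). None of these single-gene differences passed the test over all genes.

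Limma called 0 of 18820 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.13 that Cyp4a14, Cyp4a31, Arg1 and Slc37a4 had among others. At an unadjusted p under 0.05 there were 998 genes, 648 lower and 350 higher in Pcyt2+/-, where 941 would be given by chance, and after quantile normalization 540 were lower and 452 higher. As deposited, the 792 genes with a mean above 5 held 116 of the lower and 44 of the higher ones. The 18028 dimmer genes, a far larger number, held 532 and 306, so the share was higher among the brighter genes. With a trended and robust variance prior limma called 9 genes, among them Cyp4a14 (adjusted p = 0.00397), Arg1 (0.016), Cyp4a31 (0.017), Slc37a4 (0.017), Acadl (0.041) and Tat (0.042). The 9 also held Mfsd2a, Tedc2 and Atp5g3, which were named after their values were seen. Without wild type replicate 3 the count was also 9, and without Pcyt2+/- replicates 1, 2 and 3 it was 1, 2 and 1. Fits without 1 of the wild type arrays, here and for the lists, leave 1 and assume that it varies like the Pcyt2+/- arrays. An absolute log2 difference of at least 0.5 was seen for 25 genes, 19 lower and 6 higher. The group ranges did not overlap for 2417 genes, or 12.8%, where chance gives 13.3%.

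Arg1, which closes the urea cycle, had 5.33 ± 0.044 (SD, n = 4) against 6.12 ± 0.23 (SD, n = 2), a difference of -0.79, and Cps1, which opens that cycle, differed by -0.56. Mat1a, which makes S-adenosylmethionine, differed by -0.81, Ahcy, which hydrolyses S-adenosylhomocysteine, by -0.61, and Got1, the cytosolic aspartate aminotransferase, by -0.67. Lipid enzymes on that side were Elovl5, an elongase of polyunsaturated fatty acids (-0.60), and Ehhadh, of peroxisomal beta-oxidation (-0.51). Cyp2c39, a cytochrome P450, differed by -0.62. Higher in Pcyt2+/- were also Osgin1, an NRF2-responsive gene (0.76), and Ces3b, a carboxylesterase (0.54, and 0.17 without wild type replicate 3). Without wild type replicate 4 the difference was -0.43 for Got1 and -0.37 for Cps1. Of 90 named genes, 40 had a difference more than 1.5 times smaller, or of the other sign, with some 1 array left out, and for 20 it was more than 2 times smaller or turned. The naming rule required group ranges that did not overlap, so that trait of the genes of this paragraph is no support for a change. None of them passed limma over all genes (adjusted p from 0.13 to 0.913 among the 17 genes named on either side).

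**Figure D1:**
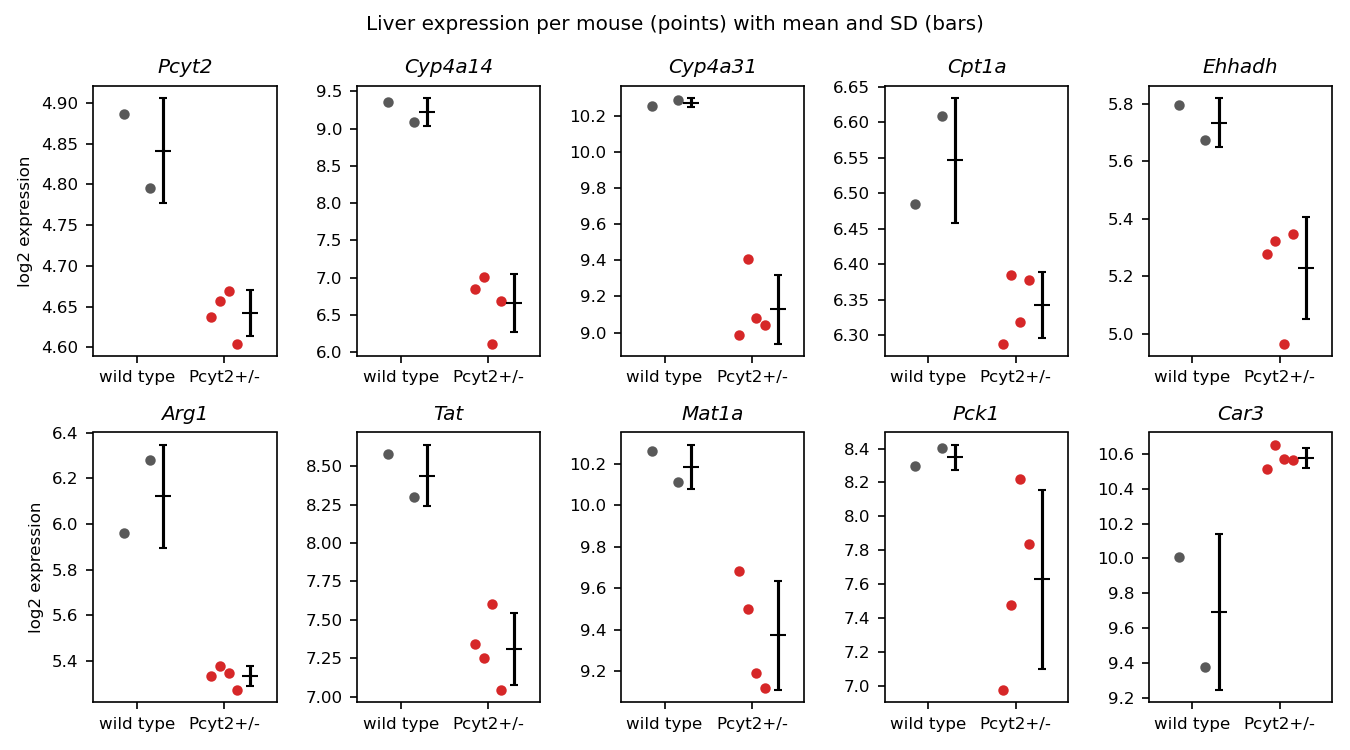
Log2 expression of 10 genes, 1 panel per gene, for the 2 wild type mice (grey points) and the 4 Pcyt2+/- mice (red points), with the group mean and SD as bars. Cyp4a14 lies between 6.11 and 7.01 on the Pcyt2+/- arrays and at 9.09 and 9.35 on the wild type arrays, while Pck1 spreads from 6.97 to 8.22 in Pcyt2+/-.

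Fatty acid oxidation genes and targets of PPARA, the nuclear receptor that drives fat burning in the liver, moved lower together. Of the 39 measured genes of this list, 38 had a lower mean in Pcyt2+/- and the median difference was -0.090. Of the 39, 21 fell, 0 rose and 18 did not pass, adjusted over the list alone, against 0 over all genes. Among those that fell were Cyp4a14 and Cyp4a31, Acadl, the long-chain acyl-CoA dehydrogenase (by 0.14), Crat, the carnitine acetyltransferase (by 0.23), and Ehhadh. Cpt1a, the rate-limiting carnitine palmitoyltransferase of mitochondrial import, fell by 0.20 (6.34 ± 0.047, SD, n = 4, against 6.55 ± 0.088, n = 2). Ppara itself had a difference of -0.051 (-0.015 without wild type replicate 4), and the 1 member with a higher mean was Fgf21, a fasting hormone at the low end of the array, with 0.011, a sign that turned without wild type replicate 3. Cyp4a10, a close relative of Cyp4a31, was not analysed here.

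Camera called this list lower with an adjusted p of 6.0e-27 over 38 lists, a value that does not measure the spread between mice. The estimated correlation of the list was 0.011, near the preset 0.01, and camera's unadjusted p went from 1.6e-28 to 0.00040 with it. Fatty acid oxidation was the 1 list that also passed with an estimated correlation (adjusted p = 0.015) and with fry (adjusted p = 0.0049). The estimated-correlation call was lost without Pcyt2+/- replicate 1 (adjusted p = 0.074), Pcyt2+/- replicate 4 (0.078), wild type replicate 3 (0.137) and wild type replicate 4 (0.186). It was also lost when only genes with a mean above 5 entered, a setting chosen after seeing the data (median -0.16, adjusted p = 0.316 with an estimated correlation).

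**Figure D2:**
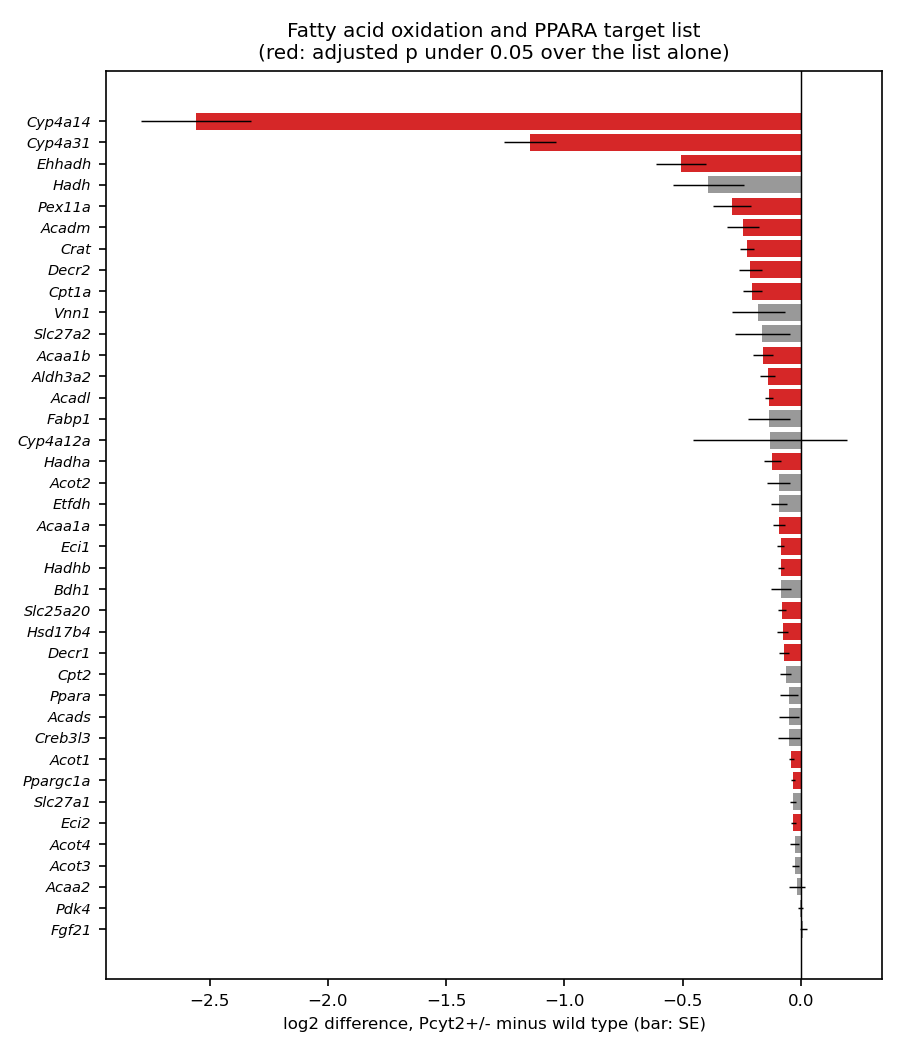
Log2 difference (Pcyt2+/- minus wild type) of the 39 measured genes of the fatty acid oxidation and PPARA target list, with the SE as black lines, and red bars for the 21 genes with an adjusted p under 0.05 over the list alone. The bars run from -2.56 for Cyp4a14 to 0.011 for Fgf21.

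Genes of cholesterol synthesis, which answer to SREBP2, were also lower. In this list of 25 measured genes, 22 had a lower mean, the median was -0.046, and 7 fell, 0 rose and 18 did not pass, adjusted over the list alone, against 0 over all genes. Tm7sf2, a sterol reductase, fell by 0.18, Ebp, a sterol isomerase, by 0.082, and Cyp51, the lanosterol demethylase, by 0.063. Fads2, a fatty acid desaturase counted in this list and in that of fatty acid synthesis, fell by 0.35. By camera the list had an adjusted p of 1.3e-10, and the call was lost with an estimated correlation (adjusted p = 0.253 with an estimated correlation).

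Fatty acid synthesis and desaturation genes were mostly on the same side. Of 26 measured genes, 4 fell, 0 rose and 22 did not pass, adjusted over the list alone, against 0 over all genes, with a median of -0.018. The 4 were Elovl5, Fads2, Fads1, the delta-5 desaturase (by 0.52), and Fasn, the fatty acid synthase (by 0.075). Scd1, the main stearoyl-CoA desaturase of the liver, had a difference of -0.46 that did not pass (-0.18 without wild type replicate 3). Srebf1, the transcription factor behind this pathway, had 4.61 ± 0.018 (SD, n = 4) against 4.61 ± 0.0055 (SD, n = 2), and the sign of its difference of -0.00024 turned with quantile normalization. The list's adjusted p by camera was 0.0013 and was lost with an estimated correlation (adjusted p = 0.369 with an estimated correlation).

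Methionine and one carbon enzymes were lower as a list with a median of -0.054 (-0.029 without Pcyt2+/- replicate 3). Of 20 measured genes, 4 fell, 0 rose and 16 did not pass, adjusted over the list alone, against 0 over all genes. They were Mat1a, Ahcy, Cth, which makes cysteine from cystathionine (by 0.23), and Gnmt, the glycine methyltransferase (by 0.22). Pemt, which methylates phosphatidylethanolamine to phosphatidylcholine, had a difference of -0.12 with an SE of 0.073 (-0.064 without wild type replicate 3). With camera the adjusted p of the list was 2.8e-05, and the call was lost with an estimated correlation (adjusted p = 0.369 with an estimated correlation).

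Glucocorticoid and fasting response genes had a median of -0.033 over 23 measured genes. Adjusted over the list alone, 4 fell, 0 rose and 19 did not pass, against 0 over all genes. These were Tat, Mt2, Klf15, a transcription factor of amino acid breakdown (by 0.077), and Angptl4, an inhibitor of lipoprotein lipase (by 0.12), with -0.049 for Klf15 and -0.071 for Angptl4 without wild type replicate 4. Camera gave this list an adjusted p of 3.4e-05, which was lost with an estimated correlation (adjusted p = 0.145 with an estimated correlation). In the list of gluconeogenesis and insulin signalling, 2 of 30 measured genes fell, 0 rose and 28 did not pass, adjusted over the list alone, against 0 over all genes, with a median of -0.013. The 2 were Slc37a4, the glucose-6-phosphate transporter (by 0.21), and Tat, which both lists hold. Pck1, the phosphoenolpyruvate carboxykinase, had a difference of -0.72 (7.63 ± 0.53, SD, n = 4, against 8.35 ± 0.075, n = 2) and G6pc, the glucose-6-phosphatase, one of -0.43 (-0.24 without Pcyt2+/- replicate 4), and neither passed. For this list camera's adjusted p was 0.0032, lost with an estimated correlation (adjusted p = 0.230 with an estimated correlation).

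Oxidative phosphorylation genes had a lower mean in 42 of 53 cases and a median of -0.029. Adjusted over the list alone, 0 fell, 0 rose and 53 did not pass by limma, as over all genes, with 10 lower and 0 higher at an unadjusted p under 0.05. Ndufv2, of complex I, had -0.26, Sdhc, of complex II, -0.18 (-0.098 without wild type replicate 3), and Atp5c1, of the ATP synthase, -0.054. Camera's adjusted p was 1.2e-06, lost with an estimated correlation (adjusted p = 0.400 with an estimated correlation) and without wild type replicate 4 (adjusted p = 0.131).

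In lipolysis and lipophagy, 3 of 13 measured genes fell, 0 rose and 10 did not pass, adjusted over the list alone, against 0 over all genes, with a median of -0.024. They were Pnpla2, the adipose triglyceride lipase (by 0.095), Ces1d, a carboxylesterase that hydrolyses triglyceride (by 0.19), and Angptl4. Camera's adjusted p was 0.0055, lost with an estimated correlation (adjusted p = 0.295 with an estimated correlation) and without wild type replicate 4 (adjusted p = 0.142). In triglyceride synthesis and lipid droplets, 0 of 28 fell, 0 rose and 28 did not pass by limma, adjusted over the list alone and over all genes, with 5 lower and 0 higher at an unadjusted p under 0.05. Dgat2, which adds the last acyl chain, had a difference of -0.23 (-0.097 without wild type replicate 3), Lpin2, a phosphatidate phosphatase, -0.12, and Cd36, a fatty acid transporter at the low end of the array, -0.019. Camera's adjusted p was 0.045 with a median of -0.012, lost with an estimated correlation (adjusted p = 0.295 with an estimated correlation) and in 5 of 6 fits that left out 1 array, the one without wild type replicate 3 excepted, with adjusted p up to 0.131.

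Most phospholipid synthesis genes were dim, with a mean above 5 for 2 of the 28. Of 28 measured genes in the Kennedy pathway list, 2 fell, 0 rose and 26 did not pass, adjusted over the list alone, against 0 over all genes. The 2 were Pcyt2 and Lpgat1, a lysophospholipid acyltransferase (by 0.076). Pcyt1a, which makes CDP-choline, had a difference of -0.0051 (0.00098 without Pcyt2+/- replicate 3). Cept1, the choline and ethanolamine phosphotransferase, had -0.031 (-0.018 without wild type replicate 3). Pisd, which makes phosphatidylethanolamine from phosphatidylserine in mitochondria, had 0.015 (0.0051 without wild type replicate 4). Camera's adjusted p was 0.045 with a median of -0.0089 (-0.0029 without wild type replicate 4). The call was lost without Pcyt2+/- replicate 3 (adjusted p = 0.167) or 4 (0.105) and with quantile normalization (0.075). It was also lost with an estimated correlation (adjusted p = 0.295), and camera's adjusted p was 0.148 without Pcyt2 itself. With the floor subtracted the list median was -0.18 (adjusted p = 0.051), over the members with a mean above 4.6. These last 2 settings were chosen after seeing the data.

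Lipoprotein, bile acid, heat shock and autophagy lists were also lower by camera, calls that an estimated correlation did not keep. Apob, the protein of VLDL particles, fell by 0.17, the 1 of 20 measured lipoprotein genes to pass, adjusted over the list alone, with 0 that rose and 19 that did not pass (median -0.066, camera adjusted p = 0.025, and 0.400 with an estimated correlation). For bile acids, 0 of 25 fell or rose by limma, adjusted over the list alone and over all genes, with 5 lower and 3 higher at an unadjusted p under 0.05 (median -0.047, camera adjusted p = 0.025, and 0.560 with an estimated correlation). The camera call was lost without Pcyt2+/- replicate 3 (adjusted p = 0.258) or 4 (0.143), and the median was -0.013 without wild type replicate 3. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had -0.30, Cyp8b1, which sets the cholic acid share, -0.76 (-0.25 without wild type replicate 4), and Slc10a1, the bile acid importer, -0.22 (-0.12 without wild type replicate 3), while Abcb11, the exporter, had 0.087. For heat shock, 0 of 16 fell or rose by limma on either adjustment, with 4 lower and 0 higher at an unadjusted p under 0.05 (median -0.014, camera adjusted p = 0.0021, 0.369 with an estimated correlation, and 0.792 without wild type replicate 4). Hspa8, the constitutive chaperone, had -0.64 there, and -0.26 without wild type replicate 4. For autophagy and lysosome, 0 of 27 fell or rose by limma on either adjustment, with 2 lower and 1 higher at an unadjusted p under 0.05 (median -0.022, camera adjusted p = 0.035, and 0.550 with an estimated correlation). Camera's call of this list was lost without Pcyt2+/- replicate 3 (adjusted p = 0.284) or 4 (0.062), and the median was -0.0095 without wild type replicate 4. Lamp2, a lysosomal membrane protein, had -0.14 (-0.079 without wild type replicate 4) and Gabarapl1, an autophagosome protein, 0.12.

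In all, 14 of the 38 lists passed with camera, each of the 14 lower in Pcyt2+/-, against 1 with an estimated correlation and 1 with fry. Among the 792 genes with a mean above 5, 62.4% had a lower mean in Pcyt2+/- (median -0.020), a balance that quantile normalization evens by construction (49.4%, median 0.0011). After it 9 of the 14 lists passed, and the male-biased liver gene list passed as higher (adjusted p = 0.015). Among 10000 random lists matched on mean expression, none had a median as low as the observed one for fatty acid oxidation (lowest random median -0.038), cholesterol synthesis (-0.022), oxidative phosphorylation (-0.026) or the glucocorticoid response (-0.029). The gluconeogenesis and Kennedy pathway lists lay at percentiles 5.27 and 5.1 of their own matched lists. Members of the random lists were drawn independently, so these percentiles do not allow for genes that vary together. Lists that camera did not call also lay low, at percentile 1.92 for immediate early genes and 2.04 for X and Y genes. With an estimated correlation camera did not call cholesterol synthesis, oxidative phosphorylation or the glucocorticoid response (adjusted p = 0.253, 0.400 and 0.145). The estimated correlation of the glucocorticoid response was 0.0017, below the preset 0.01, so a higher correlation does not account for its lost call.

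**Figure D3:**
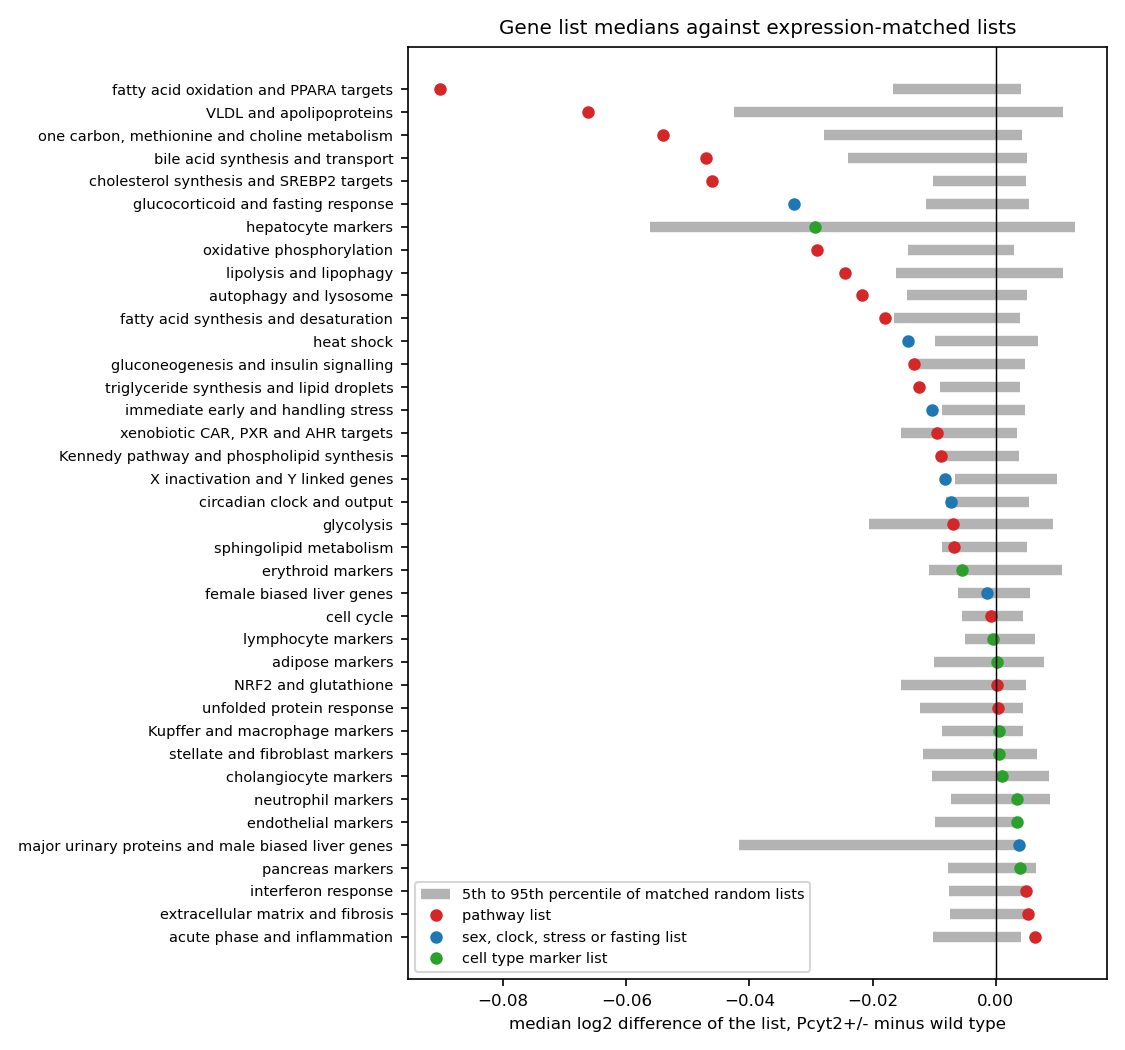
Median log2 difference (Pcyt2+/- minus wild type) of each of 38 gene lists (points, coloured by kind of list) over the 5th to 95th percentile of the medians of 10000 random lists matched on mean expression (grey bars). The fatty acid oxidation and PPARA target list lies at -0.090 with a grey bar from -0.017 to 0.0042, and the hepatocyte markers at -0.029 lie inside theirs, from -0.056 to 0.013.

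In the acute phase list of 34 measured genes, Socs2, a suppressor of growth hormone signalling, rose by 0.17, Itih4, an acute phase protein, rose by 0.25 (0.16 without wild type replicate 4), Mt2 fell, and Nfkbia, the NF-kappa-B inhibitor, fell by 0.061, adjusted over the list alone, with 30 that did not pass and 0 over all genes. The other Socs2 probe set had a difference of 0.047. Gclc, the catalytic subunit of glutathione synthesis, rose by 0.17, the 1 of 27 genes of the NRF2 and glutathione list to pass, adjusted over the list alone, with 0 that fell. At an unadjusted p under 0.05 by limma that list held 5 lower and 3 higher genes. Pkm, a pyruvate kinase, rose by 0.093, the 1 of 14 in glycolysis, with 0 that fell, and its other probe set had 0.033. C8a, a complement component, rose by 0.066, the 1 of 22 in the list of male-biased liver genes, with 0 that fell. Camera called none of these lists (adjusted p = 0.129, 0.881, 0.917 and 0.074). Over all genes limma's adjusted p was 0.310 for Gclc, 0.607 for Pkm and 0.487 for C8a. The male-biased list turned with the wild type array left out, called lower without replicate 3 (adjusted p = 0.034) and higher without replicate 4 (1.9e-09).

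Markers of the cell types that a piece of liver can hold did not pass by camera as reported. Hepatocyte markers had a median of -0.029 over 20 genes (camera adjusted p = 0.376). With the replicate block, which rests on replicates 3 and 4, camera called them lower (median -0.072, adjusted p = 0.0060). Adjusted over the list alone, 4 fell, 0 rose and 16 did not pass. The 4 were Arg1, Cps1, Apob, and Rbp4, the retinol carrier (by 0.26). Medians were 0.0011 for cholangiocyte, 0.00061 for stellate and fibroblast, 0.0035 for endothelial, 0.00049 for Kupffer and macrophage, -0.00037 for lymphocyte, 0.0034 for neutrophil, -0.0055 for erythroid, 0.0040 for pancreas and 0.00024 for adipose markers. Limma called 0 genes of these 9 lists on either adjustment, with 0 lower and 1 higher at an unadjusted p under 0.05, the pancreas gene Cela1, named after its value was seen. The cholangiocyte and the stellate and fibroblast lists each held 1 gene with a mean above 5 and the other 7 lists held 0, and this low signal limits what can be detected for these cell types.

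The other lists did not pass by camera as reported. Under other settings the unfolded protein response was called lower without wild type replicate 3 (adjusted p = 0.011) and higher without wild type replicate 4 (0.044), xenobiotic targets lower with the replicate block (0.0011), extracellular matrix higher with the dim gene filter (0.042) and immediate early genes lower without Pcyt2+/- replicate 2 (0.049). The medians of these lists as reported were 0.0052 for extracellular matrix, 0.0049 for interferon response, 0.00037 for the unfolded protein response, -0.0095 for xenobiotic targets, -0.0068 for sphingolipid metabolism and -0.00073 for cell cycle. They were -0.0073 for circadian clock, -0.010 for immediate early and handling stress, -0.0015 for female-biased genes and -0.0083 for X inactivation and Y-linked genes. For acute phase the median was 0.0063, for NRF2 and glutathione 0.00024, for glycolysis -0.0070 and for male-biased genes 0.0038. Median, mean and test differed in sign for acute phase, interferon, unfolded protein response, lymphocyte, cell cycle, adipose, and X and Y genes. The X and Y genes, at the low end of the array on all arrays, gave no reading of sex.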

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

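No test in this part was chosen after its result was seen. Dixon's test set the most extreme of the 4 Pcyt2+/- arrays against the others for 90 named genes, and 6 genes (6.67%) had an array far from the rest, against 5.72% of all genes, where chance gives about 1 in 20. Cth, which makes cysteine, had 5.17 on the array of replicate 1, with the others at 5.02 or below. Mt2, a metallothionein, had 6.07 on replicate 2, with the others between 5.16 and 5.30. Klf15, a transcription factor of amino acid breakdown, had 4.89 on replicate 4, with the others at 4.86. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 4.50 on replicate 4, with the others between 4.76 and 4.78. Hsd3b5, a male-biased steroid dehydrogenase, had 5.28 on replicate 1, with the others between 5.11 and 5.13. Stip1, a co-chaperone, had 4.43 on replicate 1, with the others between 4.39 and 4.40. The highest value on the array of replicate 1 was 13.02, with 12.87 to 12.89 on the others. Over all genes the array that stood apart was replicate 3 for 373 genes and replicates 1, 2 and 4 for 239, 225 and 240.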

How the results depend on the processing

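The settings with a mean above 5, with the array median subtracted, and with Cyp4a genes or Pcyt2 taken out of their lists were chosen after seeing the data, as was the estimated correlation in fits that left out 1 array. Without wild type replicate 3 or 4 a fit holds 1 wild type array and assumes that it varies like the Pcyt2+/- arrays. The cause was not tested where a value moved. Fewer genes were adjusted for with a mean above 5, with the floor subtracted (3248 genes) and with the dim gene filter. Pcyt2 expression was lower in Pcyt2+/- in each of 15 alternatives (-0.97 to -0.15), with limma's adjusted p from 0.0529 to 0.964. The count of genes changed in Pcyt2+/- liver was 0 as reported, 9 with the trended and robust prior, 2 with the replicate block (Cyp4a31 and Retsat), 3 with a mean above 5 and 3 with the floor subtracted (Arg1, Cyp4a14 and Cyp4a31 in both), and from 0 to 9 with 1 array left out. It was 1 without Pcyt2+/- replicate 1 (Cth), 2 without replicate 2 (Cyp4a31 and Mt2), 1 without replicate 3 (Cyp4a14), and 9 without wild type replicate 3, Arg1 and Car3 among them. It was 0 with the dim gene filter, every row of the table, the mean of a gene's rows, quantile normalization, median centring, the unmoderated statistic and array weights, and without Pcyt2+/- replicate 4 or wild type replicate 4. The number of lists past the threshold was 14 as reported, 1 with the estimated correlation, 1 with fry, 12 with the dim gene filter, 10 with quantile normalization, 17 with the replicate block, 3 with a mean above 5 (0 with a mean above 5 and the estimated correlation), 6 with the floor subtracted, and from 8 (without wild type replicate 4) to 16 (without wild type replicate 3). It was 9 without Pcyt2+/- replicate 3 and 9 without Pcyt2+/- replicate 4. Of the 14 themselves, 10 passed with the dim gene filter, 9 with quantile normalization, 14 with the replicate block, 2 with a mean above 5, 5 with the floor subtracted and 6 without wild type replicate 4. The male-biased list, not called as reported, was called higher in each of these 6 settings (adjusted p = 0.029 with a mean above 5) and without Pcyt2+/- replicate 2 (0.017), and lower without wild type replicate 3. The list of fatty acid oxidation and PPARA targets kept its direction and its side of the threshold in all but 1 of 15 alternatives: with a mean above 5 and the estimated correlation its median was -0.16 (adjusted p = 0.316). With the estimated correlation and 1 array left out it passed in 2 of 6 fits, without Pcyt2+/- replicates 2 (adjusted p = 0.041) and 3 (0.049), and not without Pcyt2+/- replicates 1 (0.074) and 4 (0.078) or wild type replicates 3 (0.137) and 4 (0.186). None of the 14 lists turned direction under any setting run, but with some 1 array left out 8 medians came more than 1.5 times nearer to 0: bile acids to -0.013, Kennedy pathway -0.0029, lipoproteins -0.026, one carbon -0.029, triglyceride synthesis -0.0063, autophagy -0.0095, heat shock -0.0072 and glucocorticoid response -0.019. Wild type replicate 4 alone ended the camera call of heat shock (adjusted p = 0.792 without it), lipolysis (0.142), oxidative phosphorylation (0.131) and fatty acid synthesis (0.054). Bile acids lost theirs without Pcyt2+/- replicate 3 (0.258) or 4 (0.143). The Kennedy pathway, lipoprotein and autophagy lists lost theirs without Pcyt2+/- replicate 3 (0.167, 0.097 and 0.284), Pcyt2+/- replicate 4 (0.105, 0.081 and 0.062) or wild type replicate 4 (0.442, 0.244 and 0.958).

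Of 1363 values of named genes under other settings, 1354 kept their direction. The sign of Srebf1 turned with quantile normalization (0.0025), with the replicate block (0.0020) and with 1 array left out (-0.0065 to 0.0075). With 1 array left out, signs also turned for Pcyt1a (-0.010 to 0.00098), Fgf21 (-0.00073 to 0.024), Pklr (-0.0017 to 0.068) and Ldhb (-0.037 to 0.0085). The shared replicate numbers 3 and 4 did not mark pairs by the labels, and the differences of replicate 3 minus 4 correlated at 0.139 across genes between genotypes. Low signal limits most genes, since 18028 of 18820 had a mean at or below 5.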

Other observations

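The tests of matched random lists, of the list without Cyp4a genes, of fasting, of sex, of the Pcyt2 ratio and of amino acid genes were chosen after the result was seen. Genes of amino acid breakdown and the urea cycle, a group put together after Arg1, Tat, Mat1a, Got1, Ahcy and Cps1 had been seen to be lower, held 33 further measured genes. Of these, 26 had a lower mean in Pcyt2+/-, with 12 lower and 1 higher at an unadjusted p under 0.05 and a median of -0.028. The lower ones included Kmo, which hydroxylates kynurenine (-0.45), Oat, the ornithine aminotransferase (-0.36), Tdo2, which opens tryptophan breakdown (-0.53), and Asl, of the urea cycle (-0.15), with -0.14 for Tdo2 and -0.10 for Asl without wild type replicate 4. Got2, the mitochondrial aspartate aminotransferase, was the higher one (0.044), and Otc, also of the urea cycle, had 0.0049 (-0.093 to 0.10 with 1 array left out). A hypothesis is that amino acid breakdown may be lower in Pcyt2+/- liver. Camera on the 33 genes gave a p of 0.0955 with an estimated correlation, so the test leaves this open. Tat, 1 of the genes that led to this group, also stands in the glucocorticoid and fasting response list. Feeding state was not given in the sources used here, so a difference in fasting cannot be told apart from an effect of genotype on these genes.

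For the lower fatty acid oxidation and PPARA target list, a lower signal of expressed genes on the Pcyt2+/- arrays is argued against by the size of the shift. The list's median was -0.090. The 10000 lists matched on mean expression had a median of -0.0066 and a lowest value of -0.038. The list's percentile of 0 adds no support, since members were drawn independently and lists that camera did not call also lay low. Immediate early genes lay at percentile 1.92 and X and Y genes at 2.04. For the fatty acid oxidation list, a signal of the Cyp4a family alone is argued against by a camera p of 0.000439 with an estimated correlation without those genes (median -0.084). A difference in sex between the groups is argued against too: over the 15 male-biased liver genes with a mean above 5 the largest difference was 0.45 in size (median 0.15), Mup20 had at least 11.18 and Cyp4a12a at least 7.41 on each array, and the highest value of a female-biased gene on any array was 4.50, although camera called the male-biased list lower without wild type replicate 3 and higher without replicate 4. Wild type mice further into fasting at collection would raise these genes and lower fatty acid synthesis in wild type. The fatty acid synthesis list was not higher in Pcyt2+/- (median -0.018, camera p = 0.0842 with an estimated correlation). The glucocorticoid and fasting response list was lower in Pcyt2+/-, which further fasting in wild type would also give. Its median was -0.033, with 18 of 23 genes lower and 5 higher (camera p = 0.0076 with an estimated correlation, adjusted p = 0.145). Fasting therefore cannot be told apart from an effect of genotype. With 15 splits a share under 0.05 is not possible, and 1 of 15 splits, the real one, had a list median as far from 0 (0.090 in size, highest other 0.057). A lower PPARA response in Pcyt2+/- liver may be the biological reading, and it stays untested beside feeding and litter, which were not given in the sources used here.

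More genes with a mean above 5 were lower than higher in Pcyt2+/- at an unadjusted p under 0.05, 116 against 44. An array-wide signal difference left by the normalization cannot be told apart from a lower level of these transcripts: after quantile normalization the counts were 91 and 94, a ratio of 0.968 against 2.64 as deposited, but that method makes the arrays equal in distribution and so evens the balance whatever its cause. For the number of genes at an unadjusted p under 0.05, 998, 4 of the 15 splits had as many, with 1184 as the highest other, and 15 splits cannot give a share under 0.05. The 1184 came from setting Pcyt2+/- replicate 3 and wild type replicate 3 against the rest. Pcyt2+/- replicate 3 had the lowest array weight (0.848), but paired with any other array it gave 689 to 1091. Replicate 4 of both groups, the other shared number, gave 718 when set apart, while Pcyt2+/- replicate 1 with wild type replicate 4 gave 1116. What a shared replicate number stands for was not given in the sources used here, and an effect of that number on this count was not tested. No biological explanation was tested for this pattern.

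Genes next to Pcyt2 held more low p-values than the rest. Of the 200 measured genes nearest to it on chromosome 11, 17 (8.5%) had an unadjusted p under 0.05, 11 lower and 6 higher, against 5.26% of the other 18619 genes (one-sided Fisher's exact p = 0.0373). A segment of another strain kept around the targeted gene may account for this, since a probe that meets a strain variant reads another signal. The test did not allow for signal level. Over all genes, 116 lower and 44 higher of the 792 with a mean above 5 had an unadjusted p under 0.05. The 18028 dimmer genes held 532 and 306, a smaller share. A larger share of brighter genes among the 200 could therefore also give the excess, and this was not tested. Only 35 measured genes came after Pcyt2 on the chromosome, so most of the 200 lay before it. The largest difference among the 200 was -0.14, and neighbouring genes are not independent of one another, so the test may overstate the excess. Shared regulation of neighbouring genes was not tested.

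The Pcyt2 signal in Pcyt2+/- was 0.871 of that in wild type as deposited, nearer to 1 than the allele number gives. With the array median taken as a floor and subtracted on the linear scale the ratio was 0.509, and with the 25th and the 75th percentile as the floor it was 0.588 and 0.331. The floor of the arrays was not given in the sources used here.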
